A study of Schmidtea mediterranea with 14 samples.

How the data were processed

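RNA came from whole Schmidtea mediterranea, a freshwater planarian flatworm, kept at 20 °C. Per the labels, RNA was taken by Trizol from control animals and from animals 6, 12, 24 or 48 h after 6000 rads of ionizing radiation. Cy3 and Cy5 cRNA was made from 1 microgram of total RNA per labelling and hybridised to 14 custom Agilent arrays of 60-base probes. There were 5 arrays at 6 h and 3 each at 12, 24 and 48 h. On each array Cy3 carried unirradiated and Cy5 irradiated RNA. No array had the dyes exchanged, so a dye bias of a probe stayed in its ratio against unirradiated animals and cancelled in differences between times. The labels called the arrays biological replicates, and the p-values rest on that. The labels did not say whether arrays shared a preparation of control RNA.

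Per the file headers, the authors used Agilent Feature Extraction 10.1.1.1. The deposited scanner files gave each spot's mean intensity and the median local background in both channels, and a processed intensity after background subtraction and dye normalization. Per the file headers, the authors' scanner software also computed the log10 of the ratio of the processed intensities, which the tests did not use. The files held flags of 0 or 1 for spots well above background, saturated or not uniform. The deposited value table held log2 ratios of Cy5 over Cy3 centred near 0, by a method that was not stated. Its identifiers did not follow the scanner's feature numbers (largest absolute r across probes 0.00729) but followed array column and row. Placed that way, 9 of its 14 columns correlated best with their own scanner file. The other 5, all at 6 h, correlated best with the file of another 6 h replicate. The mean at 6 h is not touched by an exchange within the group, but replicate numbers at 6 h are uncertain. The scanner files were used, and the value table served as an alternative.

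Of 45220 spots, 1417 were controls and 43803 were planarian probes. All 43803 probes carried the description Unknown and no gene name. The gene lists fixed for this work, which covered stem cells, DNA replication, repair, apoptosis and tissue markers, could not be matched to probes and are not reported. Probes are therefore identified by the design's own IDs. The named probes are at most 2 that rose and 2 that fell most in each comparison. They had to have an adjusted p below 0.05 and the same sign on every array of the group, or, between times, all arrays of one group above all of the other. A named probe also had to be the brightest of its transcript.

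Mean intensities were background-corrected in limma 3.58.1 (R 4.3.3 and data.table, version 1.17.8) by normexp with an offset of 50 and loess-normalized within each array, with control spots given no weight. Spots with an outlier flag were left out. A probe was tested if it was well above background in either channel on at least 3 arrays, which kept 37980 probes and left out 5823. One limma linear model with a mean per time was fitted to the log2 ratios of the 14 arrays, with empirical Bayes moderation (residual degrees of freedom 10, prior 3.88). Tests were two-sided and p-values were adjusted by Benjamini and Hochberg over the probes tested. The comparisons were each time against unirradiated animals (mean ratio against 0), 5 differences between times, and a moderated F test of any change among the times. A probe is called where the adjusted p was below 0.05. These choices, the other settings listed and the rule for named probes were fixed before the data were examined. Groups of probes by time course were defined afterwards. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

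Loess sets the centre of each array's ratios near 0, so a change shared by all transcripts cannot be seen, and ratios are relative to the other transcripts. The number of arrays limits the precision. The median over 206 pairs of probes with identical sequence of the SD between arrays of their difference was 0.084 in log2. On simulated data with the real residual spread and 200 changed probes, a change of 0.5 in log2 was recovered for 94% of probes at 6 h and 50.7% between 48 and 24 h. A change of 1 was recovered for 98.5% and 86.6%. Between 24 and 12 h the shares were 43.3% for a change of 0.5 and 94% for a change of 1. The simulation gave all arrays of a probe the same spread, while the 12 h arrays were the least alike (r across probes 0.359 to 0.56). The shares may therefore not hold for comparisons with 12 h. With only 200 changed probes the adjusted threshold is also stricter than where many more are called.

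After the gene lists had failed to match, probe sequences were translated and searched for conserved protein motifs. The median log2 ratio of a motif's probes was set against 10000 random lists matched on intensity in 20 bins, and tested by limma's camera and fry. Camera compares a list with the other probes, and fry tests it without them.

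Whether replicate numbers pair arrays was checked by correlating residual profiles of arrays with the same number. Each same-number pair exceeded 0.1 for 24 against 6 h (r across probes 0.305 to 0.614) and for 24 against 12 h (0.187 to 0.448). This was not so for the other differences. Over all times, the 18 same-number pairs had a mean r of 0.275 (−0.086 to 0.614) and the 54 other pairs −0.091 (−0.709 to 0.469). The reported fit treated the arrays as independent and did not model this. The labels state no pairing, so the replicate number entered as a block only as an alternative.

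The arrays lay on 4 slides read on 2 days. Slide 1 held 6 h replicates 4 and 5. Slide 2 held 12 h replicates 2 and 3 with 24 h replicates 1 and 2. Slide 3 held 24 h replicate 3 with the 3 arrays at 48 h. Slide 4 held 6 h replicates 1 to 3 with 12 h replicate 1 and was read on another day. Differences between times were refitted with slide as a block, and neighbouring times also within 1 slide.

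The other settings fixed in advance were no background correction, the processed intensities, median centring, no normalization, quantile normalization of intensities, other filters, a trended robust prior and only the arrays compared. Replicate, slide and scan-day blocks, the value table, a limit of 2-fold, an adjusted p below 0.01 and leaving out each array were also fixed in advance. Added after the data were seen were slide as a fixed block, fits within 1 slide, only arrays with a spike-in slope of at least 0.85, array weights, and outlier spots kept.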

Results

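Transcript levels of whole planarians were compared between unirradiated animals and animals that had received 6000 rads. Ionizing radiation kills the dividing cells of planarians, the neoblasts, on which tissue renewal depends, and the series followed the transcript changes over the first 48 h. Irradiated and unirradiated RNA were hybridised together on 14 two-colour arrays, 5 at 6 h and 3 each at 12, 24 and 48 h. On each array 29797 to 37437 of 43803 probes were well above background in at least 1 channel. Median signal ran from 81.8 to 236.9 in Cy3 and from 130.0 to 446.4 in Cy5, against local backgrounds of 22 to 26 and 49 to 57. No spot was saturated. Values below are log2 ratios of irradiated over unirradiated animals, with the SD over arrays, and adjusted p-values are from limma. Because no gene names came with the design, probes are described by their time courses and IDs.

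The first question was what had changed 6 h after irradiation. Relative to the other transcripts, probes that moved by at least 2-fold were mostly lower: 1015 fell and 21 rose. With median centring 1117 were lower and 52 higher, but without normalization 106 were lower and 16246 higher. The median of all probes was then 0.968. Unnormalized ratios keep any difference in overall signal between the channels, so their counts, here and at later times, cannot alone give a direction of change. SMED_12382_V2_1 fell to −2.92 ± 0.91 (SD, n = 5), which is 7.56-fold, with an adjusted p of 2.82e-05. SMED_01303_V2_1 fell to −2.87 ± 0.79 (SD, n = 5), or 7.33-fold (adjusted p 5.65e-06). SMED_08717_V2_1 (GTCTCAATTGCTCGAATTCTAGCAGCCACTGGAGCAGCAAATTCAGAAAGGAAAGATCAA) rose most, to 2.75 ± 0.29 (SD, n = 5), or 6.74-fold (adjusted p 7.63e-08). SMED_02793_V2_1 rose to 1.64 ± 0.33 (SD, n = 5), or 3.12-fold (adjusted p 3.19e-07). These 4 probes had the same sign on all 5 arrays. At any size, 16807 of 37980 probes were called, 9947 lower and 6860 higher, and the median absolute log2 ratio of the called probes was 0.273. Within slide 4 (3 arrays) 15925 probes were called and within slide 1 (2 arrays) 9386, and 15725 with slide as a random block. That block used 1 correlation within slides for all probes, estimated at 0.0442, so it could change counts little, here and at later times. The share of called probes that were lower was 59.2%, but it was 39.3% on the scanner's processed signals and 1.16% without normalization.

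At 12 h 75 probes were lower by at least 2-fold and 12 were higher. The 75 became 28 without replicate 1 and 188 without replicate 3, and without replicate 2 the count lay above 75 and below 188. With median centring 0 were lower and 16 higher, by limma, and without normalization 4 were lower and 3277 higher. SMED_08717_V2_1 was again the probe with the largest rise, at 2.38 ± 0.52 (SD, n = 3; limma adjusted p 8.61e-06). SMED_00106_V2_1 rose to 1.96 ± 0.24 (SD, n = 3; limma adjusted p 2.21e-06). SMED_18752_V2_1 fell to −1.94 ± 0.48 (SD, n = 3; limma adjusted p 1.11e-05), and SmWIOct06_023556 fell to −1.85 ± 0.75 (SD, n = 3; limma adjusted p 0.0043). In all, 4348 probes were called, 1594 lower and 2754 higher (36.7% lower, but 52.1% without background correction). The 3 arrays at 12 h were the least alike, with r across probes of 0.359 to 0.56, and 12 h replicate 1 correlated at 0.844 on average with the 6 h arrays. With only the 12 h arrays in the fit 11 probes were called, without replicate 1 there were 2437, and without background correction 13325. With slide as a random block 3837 were called, and within slide 2 (2 arrays) limma called 0, with 3981 at an unadjusted p under 0.05.

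At 24 h, 475 probes were lower by at least 2-fold and 48 were higher. Without normalization 198 were lower and 935 higher. SMED_01626_V2_1 fell to −3.34 ± 0.04 (SD, n = 3; limma adjusted p 4.74e-05). SmWIOct06_100020 (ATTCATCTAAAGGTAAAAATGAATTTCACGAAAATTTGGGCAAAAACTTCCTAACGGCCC) fell to −3.22 ± 0.05 (SD, n = 3), or 9.33-fold (limma adjusted p 1.97e-06). The largest rises were those of SMED_05729_V2_1, 1.44 ± 0.15 (SD, n = 3; limma adjusted p 5.03e-09), and SMED_14642_V2_1, 1.37 ± 0.14 (SD, n = 3; limma adjusted p 7.24e-07). In all, 12476 probes were called, 6456 lower and 6020 higher. Higher probes were the larger part with median centring (1076 against 761), on processed signals (7612 against 5859) and without normalization (7035 against 271). Within slide 2 (2 arrays) 13238 were called, and 12064 with slide as a random block.

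At 48 h, 863 probes were lower by at least 2-fold and 83 were higher, 44 of them reverse-complement probes. Without normalization 285 were lower and 1867 higher. SmWIOct06_100020 had fallen to −4.45 ± 1.3 (SD, n = 3), or 21.8-fold (limma adjusted p 5.68e-08). Replicates 1 to 3 had −4.34, −3.21 and −5.8, with slopes of observed on expected spike-in ratios of 0.716, 0.662 and 0.889. At 6 h these slopes were 0.900 to 0.928, so sizes of change may not be comparable between times. Whether the slopes account for the SD was not tested. SMED_28943_V2_1 (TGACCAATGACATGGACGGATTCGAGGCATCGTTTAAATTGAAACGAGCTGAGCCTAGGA) had fallen to −4.43 ± 0.96 (SD, n = 3), or 21.6-fold (limma adjusted p 4.26e-09). The largest rise was that of SMED_35739_V2_1 (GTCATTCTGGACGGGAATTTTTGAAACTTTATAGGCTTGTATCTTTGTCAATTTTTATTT), 2.47 ± 0.07 (SD, n = 3), or 5.53-fold (limma adjusted p 4.24e-12). SMED_02253_V2_1 rose to 2.32 ± 0.05 (SD, n = 3; limma adjusted p 5.62e-12); it shares 57 of its 60 bases with the probe before, so these 2 are not independent. In all, 16273 probes were called, 8519 lower and 7754 higher, but higher ones were the larger part with median centring (1773 against 1265), on processed signals (10216 against 7329) and without normalization (8100 against 379). The 3 arrays all lay on slide 3, so the 13776 called with only these arrays cannot test an effect of slide. With slide as a random block the count was 15553. On arrays with a spike-in slope of at least 0.85, which kept 1 of the 3, it was 8627.

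**Figure D1:**
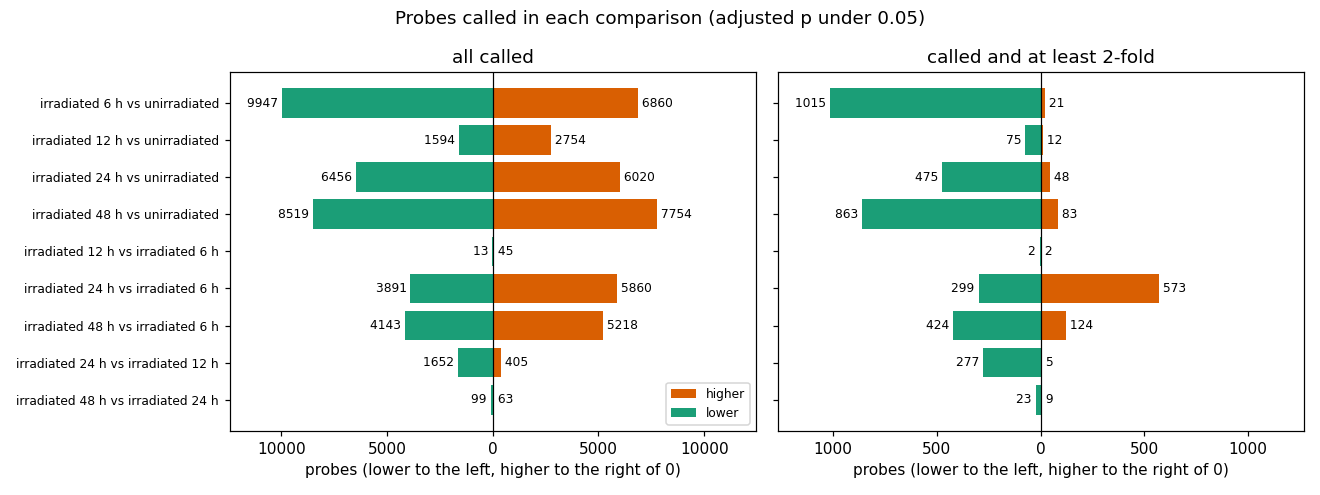
Number of probes called in each comparison by limma, lower to the left and higher to the right, at any size and at 2-fold or more. With the loess normalization used here, lower probes outnumbered higher ones at 2-fold or more at each time against unirradiated animals (1015 against 21 at 6 h). Without normalization, which keeps any signal difference between the channels in the ratios, higher ones outnumbered lower ones at each time (16246 against 106 at 6 h). At 12 h they did so with median centring too (16 against 0).

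The fall of at least 2-fold took different courses over time. A group of 740 probes was lower at 6 h by at least 2-fold and higher at 24 h than at 6 h, here called the early fall. With slide as a fixed block 1 of the 740 was still called between 24 and 6 h, with a median difference of 0.43 against 1.12 without it. Their median was −1.33 ± 0.38 at 6 h (SD of array medians, n = 5), −0.55 ± 0.37 at 12 h, −0.23 ± 0.34 at 24 h and −0.68 ± 0.12 at 48 h (n = 3 each). Another group of 570 probes, the late fall, was lower at 48 h by at least 2-fold and lower than at 6 h. Their median was −0.29 ± 0.06 at 6 h, −0.29 ± 0.19 at 12 h, −1.29 ± 0.08 at 24 h and −1.58 ± 0.13 at 48 h. Lower by at least 2-fold at both 6 and 48 h were 247 probes; 139 of these belong to the early fall and 19 to the late fall. A late rise was seen for 77 probes, from 0.29 ± 0.13 at 6 h to 1.13 ± 0.10 at 48 h; 44 of the 77 were reverse-complement probes. These groups were defined after the data were seen, from the same arrays, so their medians describe them and do not test them. The early fall held 462 probes without 24 h replicate 3 and 491 without 6 h replicate 2. With median centring, no normalization and processed signals it held 13, 8 and 1556, and 1172 with the deposited value table. With the first 3 of these settings the late fall held 258, 221 and 884, the probes lower at both times were 61, 1 and 547, and the late rise held 37, 13 and 320. The 740 probes, picked with loess, had a median 24 minus 6 h difference of 1.35, 0.76 and 1.21 with these 3 settings, against 1.12 with loess. The counts of 13 and 8 therefore do not by themselves show that the difference was lost.

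**Figure D2:**
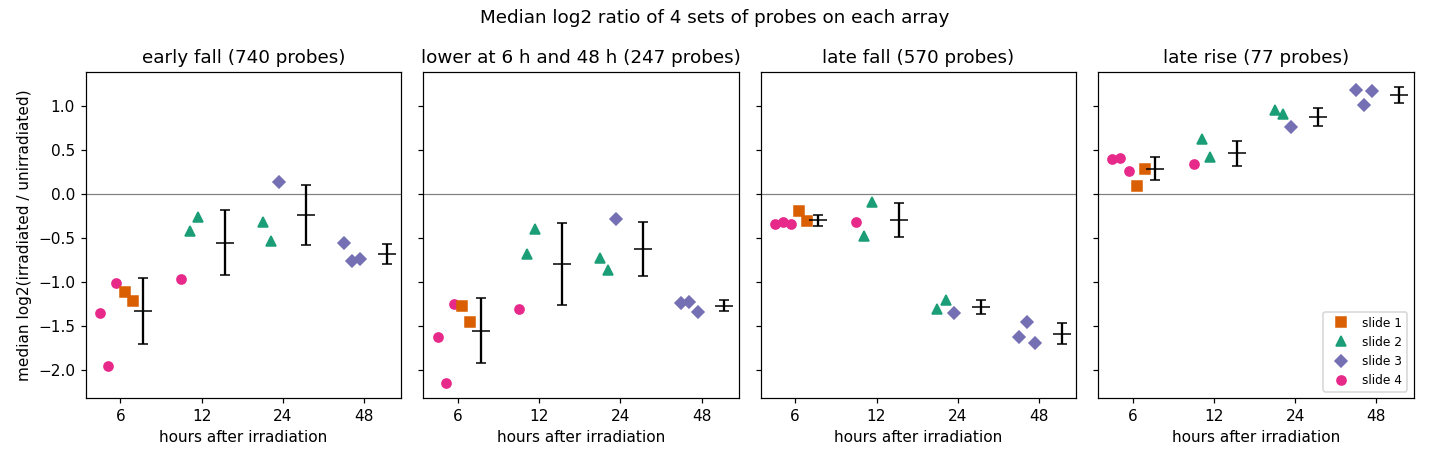
Median log2 ratio of irradiated over unirradiated animals on each array (points, coloured by slide) for 4 groups of probes at 6, 12, 24 and 48 h, with bars for the mean and SD of the array medians. The early fall was at −1.33 at 6 h and −0.23 at 24 h, and the late fall at −0.29 and −1.29.

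Whether the profile moved between times was tested directly, and 10441 of 37980 probes (27.5%) passed the F test of any change among the 4 times. With slide as a fixed block 364 passed, with scan day as a block 6462, with median centring 371 and without normalization 740. In the fit with slide as a fixed block, 12 h replicate 1 is the only array that links 6 h to the later times, so its values for 12, 24 and 48 h against 6 h rest on that array.

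Between 12 and 6 h, 58 probes differed, 45 higher and 13 lower at 12 h, but 34 were higher and 66 lower on processed signals. SMED_07471_V2_1 stood at 0.85 ± 0.49 (SD, n = 3) at 12 h against −0.81 ± 0.49 (SD, n = 5) at 6 h (limma adjusted p 0.0247). SMED_05778_V2_1 was higher at 12 h by 1.2 (limma adjusted p 0.0172). SMED_02480_V2_1 was at 0.44 ± 0.04 (SD, n = 3) at 12 h and at 1.54 ± 0.18 (SD, n = 5) at 6 h (limma adjusted p 0.000801), and SMED_08508_V2_1 differed by −1.04 (limma adjusted p 0.00749). With slide as a fixed block limma called 0 probes, with 1669 at an unadjusted p under 0.05, and within slide 4, with 1 array at 12 h, it called 0, with 1894. The differences of the 4 named probes were then 2.33, 1.16, −1.04 and −0.88 in both fits, against 1.66, 1.2, −1.1 and −1.04. Without 12 h replicate 1 the count was 2788, without replicate 2 it was 1, without replicate 3 it was 5, and with replicate number as a block 2665.

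Between 24 and 6 h, 9751 probes differed, 5860 higher and 3891 lower at 24 h. This balance turned with median centring (61 higher, 172 lower), without normalization (28 and 1358) and on processed signals (5792 and 6666). SMED_08239_V2_1 was at −0.02 ± 0.89 (SD, n = 3) at 24 h and at −2.55 ± 0.57 (SD, n = 5) at 6 h (limma adjusted p 0.00293). SMED_12382_V2_1, which fell most at 6 h, was higher at 24 h by 2.52 (limma adjusted p 0.00604). In the other direction, SMED_04546_V2_1 was at −3.08 ± 0.08 (SD, n = 3) at 24 h and at −0.01 ± 0.12 (SD, n = 5) at 6 h (limma adjusted p 9.21e-06), and SMED_01626_V2_1 differed by −3.17 (limma adjusted p 0.00115). No slide held both times, and with slide as a fixed block 141 probes were called, 131 of them lower. The difference was then 0.03 for SMED_08239_V2_1 and 0.21 for SMED_12382_V2_1, but −2.82 for SMED_04546_V2_1 (adjusted p 0.127) and −2.84 for SMED_01626_V2_1 (adjusted p 0.549), so none of the 4 was called. Without 24 h replicate 3 the count was 5909, and with scan day as a block 5571.

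Between 48 and 6 h, 9361 probes differed, 5218 higher and 4143 lower at 48 h. Here too the balance turned with median centring (145 higher, 360 lower), without normalization (13 and 868) and on processed signals (4988 and 5550). SMED_06445_V2_1 was at 2.00 ± 0.31 (SD, n = 3) at 48 h and at −1.02 ± 0.37 (SD, n = 5) at 6 h (limma adjusted p 1.36e-07). SMED_35739_V2_1 was higher at 48 h by 2.45 (limma adjusted p 8.98e-11). SMED_04153_V2_1 was at −4.41 ± 1.04 (SD, n = 3) against −0.06 ± 0.06 (SD, n = 5) at 6 h (limma adjusted p 2.95e-07), and SMED_04546_V2_1 differed by −4.24 (limma adjusted p 1.89e-07). No slide held both times, and 178 probes were called with slide as a fixed block, with SMED_35739_V2_1 at 2.55 (adjusted p 0.000682). The differences of the other 3 were then 2.74, −4.22 and −3.94, with adjusted p of 0.0771, 0.0811 and 0.0818.

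Between 24 and 12 h, 2057 probes differed, and 1652 of these were lower at 24 h. SMED_04546_V2_1 differed by −3.01 (limma adjusted p 5.62e-05) and SMED_01626_V2_1 by −2.9 (limma adjusted p 0.0128). Of the 570 probes of the late fall, 463 were called lower at 24 than at 12 h. SMED_06445_V2_1 and SMED_35739_V2_1 were higher by 1.23 and 1.11 (limma adjusted p 0.00407 and 2.27e-06). With slide as a fixed block 745 probes were called and within slide 2, which held 2 arrays of each time, 215. The differences with the block were −2.9 for SMED_04546_V2_1 (adjusted p 0.00641), −2.78 for SMED_01626_V2_1 (adjusted p 0.149, but adjusted p 0.00203 within slide 2), 1.14 for SMED_06445_V2_1 (adjusted p 0.0878, and adjusted p 0.111 within slide 2) and 1.15 for SMED_35739_V2_1 (adjusted p 0.000307). Without 12 h replicate 2 the count was 4218, and without 12 h replicate 3 it was 1009.

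Between 48 and 24 h, 162 probes differed, 63 higher and 99 lower at 48 h, but 117 were higher and 102 lower on processed signals. SMED_01436_V2_1 was at −3.59 ± 0.47 (SD, n = 3) at 48 h and −1.03 ± 0.04 (SD, n = 3) at 24 h (limma adjusted p 3.21e-06). SmWIOct06_000297 was at −2.53 ± 0.08 (SD, n = 3) and −0.53 ± 0.09 (SD, n = 3; limma adjusted p 7.23e-09). SMED_04485_V2_1 was at 1.93 ± 0.23 (SD, n = 3) and 0.34 ± 0.09 (SD, n = 3; limma adjusted p 1.97e-05), and SMED_15891_V2_2 was higher by 1.4 (limma adjusted p 1.25e-05). With median centring limma called 2, both higher and neither of them named here. With slide as a fixed block 36 probes were called and within slide 3, with 1 array at 24 h, 6. Without 24 h replicate 1 or 2 the count was 61, and without 12 h replicate 2 it was 348.

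**Figure D3:**
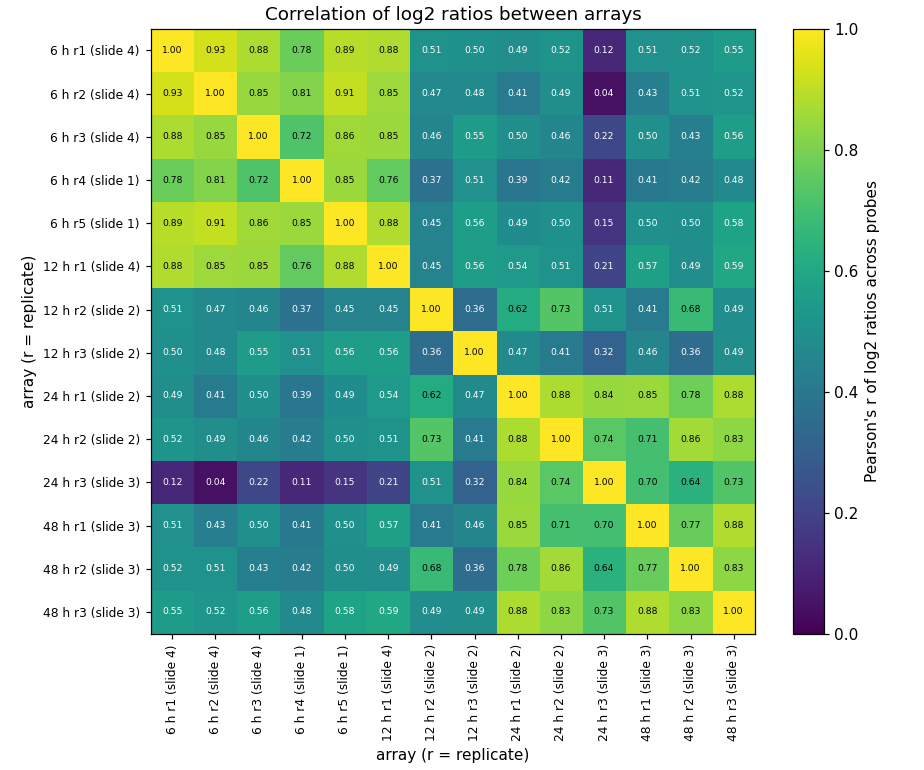
Pearson correlation across probes of the log2 ratios of each pair of the 14 arrays, ordered by time. Arrays at 24 and 48 h resembled one another (mean r 0.774) more than arrays at 6 and 24 h did (mean r 0.355). Probes are not independent replicates.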

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

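The tests of 12 h replicate 1, of slides and of dye bias were chosen only after the results were seen. The other tests were set before their results were seen.

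Ratios differed between times in the fit without slides, and slide and time largely coincide. The test of any change passed 10441 probes (364 with slide as a fixed block), and the differences between times called 9751 (24 against 6 h; 141 with the block), 9361 (48 against 6 h; 178), 2057 (24 against 12 h; 745), 162 (48 against 24 h; 36) and 58 (12 against 6 h; 0, with 1669 at an unadjusted p under 0.05, by limma). Against unirradiated animals, 366 probes were called lower at 6 h and higher at 48 h and 414 the opposite way.

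A sample stood apart at 6 h in 2 of the 36 sets of 5 arrays examined (gap over range above 0.71), where chance gives about 1 in 20. For SMED_05778_V2_1 replicate 2 was at −1.87 and the others at −1.16 to −1.01. For the median of the late fall replicate 4 was at −0.19 and the others at −0.34 to −0.3.

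Other groupings of the arrays were counted. Of the 56 splits of the 6 and 24 h arrays, 1, the real one, called 9751 probes, and the highest other called 21 in a split that put the 6 h arrays of slide 4 together. Same-number arrays correlated at 0.305 to 0.614 here, but the labels state no pairing and replicate numbers at 6 h are uncertain. With the 6 h numbers of the value table the correlations were −0.306, −0.229 and −0.415. If the arrays are pairs, the 8 splits that part 3 pairs (real 9751, highest other 21) are too few for a share under 0.05. For 48 against 6 h 1 of 56 splits, the real one, called 9361 (highest other 15), a share under 0.05 where single arrays are exchanged. Same-number arrays correlated at 0.087 to 0.179 there, so a weak pairing is not excluded. The splits do not address slides: no slide held both 6 and 48 h, and with slide as a fixed block the count was 178. For any change 1 of 100 regroupings, the real one, reached 10441 (highest other 1635), a share under 0.05 where single arrays are exchanged. These regroupings ignored any pairing by replicate number, which the labels do not state and the residual correlations leave possible. They do not separate time from slide, and with slide as a fixed block 364 passed. For 12 against 6 h, 2 of 56 splits called as many as the real 58, a share under 0.05. The other one called 368, several times the real count. It put 6 h replicate 4 with 12 h replicates 2 and 3, all read on the same day, against the 4 arrays of slide 4 and 6 h replicate 5. Thus it is the real split with 12 h replicate 1 and 6 h replicate 4 exchanged. The split points to a structure of the samples other than time, in which scan day may have a part. Scan day does not fully match it, since 6 h replicate 5 was read on the same slide and day as 6 h replicate 4. The remaining designs give too few splits or sign changes for a share under 0.05: 6 h (1 of 16, real 16807, highest other 5), 12 h (1 of 4, 4348, 0), 24 h (1 of 4, 12476, 0), 48 h (1 of 4, 16273, 143), 24 against 12 h (1 of 10, 2057, 0) and 48 against 24 h (1 of 10, 162, 0).

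The early fall of 740 probes at 6 h and its smaller size at 24 h could come from other control RNA on the 6 h slides or from a slide or scan batch. Against other control RNA, a median of 13.6% of the change in ratio lay in the Cy3 channel, which carried unirradiated RNA (147 of the 740 probes exceeded 50%). Relative to the mean over arrays, the median Cy3 level of these probes in replicate 3 was −0.36, −0.64, −0.44 and −0.33 at 6, 12, 24 and 48 h. In replicates 1 and 2 it was 0.06 to 0.33 at all times, and in 6 h replicates 4 and 5 it was 0.33 and −0.1. Whether arrays of the same number shared control RNA was not tested. Against a batch of 1 slide or scan day as the whole of the 6 h fall, 1347 probes picked on the 6 h arrays of slide 4 (median −1.29) had a median of −0.97, or 75.2%, on those of slide 1, and 642 picked on slide 1 (−1.25) had −1.52 on slide 4. For the higher ratio at 24 h a batch cannot be told apart from time: with slide as a fixed block 38.2% of the median difference was kept (1.12 before, 0.43 after), but that fit links the times through 12 h replicate 1 alone, itself in doubt. For the late fall, slide 2, whose arrays did not pick these probes, held a median difference of −0.93 between 24 and 12 h, 75.6% of that between 48 and 6 h, lower in 556 of 557 probes, which argues against a batch as its whole source.

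At 12 h, replicate 1 resembled the 6 h arrays, with a mean r across probes of 0.844, inside the 0.791 to 0.877 of the 6 h arrays among themselves. Replicates 2 and 3 had 0.452 and 0.519. A shared slide is argued against, since replicate 1 correlated only 0.042 more with 6 h arrays of its own slide than with those of the other. A 6 h profile in the sample itself, by its timing or its label, may account for it and stays open. So does spread between animals at 12 h, which was not tested. Array quality is a further limit: 12 h replicates 2 and 3 had spike-in slopes of 0.751 and 0.770, with 401 and 402 outlier spots. Replicate 1 had a slope of 0.892 and 3 outlier spots, and at 12 h it alone met the slope limit of 0.85. Without this array 2788 probes differed between 12 and 6 h.

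Called the same way at all 4 times were 922 lower and 1386 higher probes, as a fixed dye bias could produce, because Cy5 carried irradiated RNA on each array. Direction was related to the G count of the probe (Spearman rho −0.274), as dye bias would need. Of the lower probes, 56.2% passed the test of any change, where probes of like residual spread passed at 30.7% (excess 25.5, jackknife SE over arrays 5.55). A difference between slides could do the same, and with slide as a fixed block 37.7% of them against 15.2% had an unadjusted p under 0.05 (excess 22.5, SE 13), which decides nothing. Of the higher probes, 30.5% against 28% passed (excess 2.56, SE 7.07). Dye bias and a lasting response therefore cannot be told apart in either direction, since no array had the dyes exchanged.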

How the results depend on the processing

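Slide as a fixed block, fits within 1 slide, arrays with a spike-in slope of at least 0.85, array weights and outlier spots kept were chosen after the data were seen. For 36 results on named probes, 1184 values were recomputed: 1110 stayed on the same side of the threshold with the same direction, 74 lost the call, and 0 reversed. Quantile normalization and the 2-fold limit could move none of them, and without these 2 settings 1038 of 1112 stayed. The named probes were picked as the most extreme on these same data, which favours keeping the call. Kept were 20 of 36 with median centring, 25 of 36 without normalization and 7 of 20 with slide as a fixed block. Counts moved by over 1.5 times as follows, and the cause was not tested unless given. Without background correction: 13325 (12 h), 89 (12 against 6 h), 359 (48 against 24 h). With processed intensities: 13214 and 100 for the first 2 of these. With the value table: 13220, 88 and 354. With median centring: 4229 (6 h), 41 (12 h), 1837 (24 h), 3038 (48 h), 0 (12 against 6 h), 233 (24 against 6 h), 505 (48 against 6 h), 121 (24 against 12 h), 2 (48 against 24 h), 371 (any change). With no normalization, in this order: 28372, 11149, 7306, 8479, 0, 1386, 881, 115, 7, 740. With at least 2-fold, a stricter limit by construction: 1036, 87, 523, 946, 4, 872, 548, 282, 32, 986. With adjusted p below 0.01, also stricter: 1498 (12 h), 8159 (24 h), 3 (12 against 6 h), 5536, 5182, 864, 62 and 5502 (any change). With only the arrays compared, fewer arrays: 11 (12 h), 1 (12 against 6 h), 718 (24 against 12 h), 70 (48 against 24 h). The replicate block gave 2665 (12 against 6 h), and the scan-day block 27 (12 against 6 h), 5571, 6132 and 6462 (any change). Slide as a fixed block, which rests on 12 h replicate 1 for differences from 6 h, gave 0 (12 against 6 h), 141, 178, 745, 36 and 364 (any change). Within 1 slide: 0 (12 against 6 h), 215 (24 against 12 h), 6 (48 against 24 h). With the spike-in limit, fewer arrays: 828 (12 h), 8627 (48 h), 0 (12 against 6 h), 3927 (48 against 6 h), 1288 (24 against 12 h), 5008 (any change). With array weights: 29 (12 against 6 h), 3480 (24 against 12 h), 541 (48 against 24 h). The counts of 0 for 12 against 6 h, all by limma, had 5466 (median centring), 655 (no normalization), 1669 (slide block), 1894 (within slide 4) and 1231 (spike-in limit) at an unadjusted p under 0.05, and 6388 in the reported fit. Leaving out 1 array gave 12890 to 17708 (6 h), 2437 to 4760 (12 h), 8328 to 13214 (24 h), 12044 to 17062 (48 h), 1 to 2788 (12 against 6 h), 5909 to 10716 (24 against 6 h), 6451 to 10211 (48 against 6 h), 1009 to 4218 (24 against 12 h), 61 to 348 (48 against 24 h) and 8152 to 11419 (any change). Arrays whose removal moved a count by over 1.5 times were 12 h replicate 1 (2437 at 12 h) and 24 h replicate 3 (5909 for 24 against 6 h). For 12 against 6 h they were 6 h replicates 1 to 4 (9, 27, 21, 30), 12 h replicates 1 to 3 (2788, 1, 5) and 24 h replicates 1 and 2 (38, 38). For 24 against 12 h they were 12 h replicates 1 to 3 (1297, 4218, 1009) and 24 h replicates 1 and 3 (1191, 1093). For 48 against 24 h they were 6 h replicates 1 and 5 (94, 101), 12 h replicate 2 (348), 24 h replicates 1 to 3 (61, 61, 85) and 48 h replicate 1 (67). The share lower depends on the scaling: 59.2% at 6 h became 71.4% (median centring), 39.3% (processed) and 1.16% (none), and 52.4% at 48 h became 41.6%, 41.8% and 4.47%. At 12 h 36.7% became 49.9% (value table), 52.1% (no background correction), 0% of 41 (median centring) and 0.0359% (none). At 24 h 51.7% became 41.4% (median centring) and 3.71% (none). Without normalization the median of all probes was 0.968, 0.284, 0.391 and 0.392 at the 4 times, and with median centring 0.115 at 12 h. Relative to the median of all probes the early fall at 6 h was −1.3, −1.39, −1.38, −1.47 and −1.4 with loess, median centring, none, processed and value table, and the late fall at 48 h −1.57, −1.48, −1.49, −2.14 and −1.66. Quantile normalization of intensities leaves log ratios as they were, so it tests nothing. The 2 gene-list alternatives were not run because no list could be matched. Signal over background limits dim probes: 5823 were not tested.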

Other observations

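The test of actin signatures and the tests by probe class were chosen after the data were seen. The histone and strand tests were set before their results were seen.

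Probes from the smaller source set with SmWIOct06 IDs were lower by at least 2-fold more often than the forward SMED probes late in the course. The shares were 3.34% against 2.87% at 6 h (Fisher's exact odds ratio 1.17, adjusted p 0.236), 5.35% against 1.1% at 24 h (5.07, 2.64e-34) and 7.66% against 2.13% at 48 h (3.82, 1.26e-35). Probes are not independent, within or between transcripts, and were read on the same arrays, so these p-values do not measure the spread between animals. What the set was chosen for is not stated. Among probes higher by at least 2-fold, reverse-complement probes of the SMED set were 25 of 48 at 24 h and 44 of 83 at 48 h. An early rise was rare with loess normalization, where 21 probes were higher by at least 2-fold at 6 h. On processed signals 218 were, and without normalization 16246. Of the 21, 12 were lower at 24 h than at 6 h. Their array medians were 1.30 ± 0.08 at 6 h (SD, n = 5) and −0.04 ± 0.03 at 48 h (SD, n = 3).

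Transcripts could be placed in a protein family only where the probe's own 60 bases encode a conserved motif. Core histone motifs were found in 10 tested probes. The hypothesis was that these fall with the loss of dividing cells by 48 h. Their median log2 ratio was −0.11 at 48 h, at percentile 11 of random lists matched on intensity, so the prediction (below percentile 5) was not met. There 4 were called lower and 1 higher. At 24 h the percentile was 2.7 with 4 lower, and camera gave adjusted p 0.00937 with a preset correlation of 0.01 and adjusted p 0.226 with an estimated correlation. At 48 h camera gave adjusted p 0.0531 and 0.282. By fry the histone probes were lower at 24 h (adjusted p 1.13e-05) and 48 h (adjusted p 6.06e-05) but higher at 6 h (adjusted p 0.042). Fry does not set them against the other probes. Of 5 probes with actin motifs, 4 were called lower at 6 h, at percentile 3.27, but camera, on the 4 probes without missing values, gave adjusted p 0.127 there with the preset correlation and adjusted p 0.324 with an estimated one. At 12 h 3 were called lower, at percentile 2.29, with camera adjusted p 0.032 and adjusted p 0.31 with an estimated correlation. Fry on the same 4 probes gave adjusted p 0.000114 at 6 h and adjusted p 0.00427 at 12 h.

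Forward and reverse-complement probes of the same sequence were both tested in 2796 pairs. If 1 transcript were read on both strands, the weaker strand should follow the stronger. At 48 h Spearman's rho across pairs was 0.492, between the limits set in advance. It was 0.70 in the 2064 pairs at least 2 apart in log2 intensity and 0.0302 in the 531 pairs less than 1 apart. Antisense transcription and reading of 1 transcript on both strands cannot be told apart for these pairs. Of the 891 pairs called on both strands, 558 had the same direction.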
